A study of Mus musculus with 18 samples.

How the data were processed

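Total RNA of mouse embryonic fibroblasts was measured on 18 Affymetrix mouse gene arrays, 3 per group, in 6 groups set by the titles and treatment labels: WT in isotonic or hypertonic medium, each with or without Torin1, and Nfat5 KO in isotonic or hypertonic medium. The deposited values are RMA signals on the log2 scale, made with R 2.11.1 per the submitters' processing notes. They cover 34760 probe sets and were used as they are, with no further normalization. The genome build is not given in the sources used here, and the gene table of the assembly GRCm38.p6 served only for current gene names and for which genes are neighbours or overlap.

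Of the probe sets 21640 name 1 gene, 1321 name several and 11799 have no annotation. Each of 19937 genes was taken as its probe set with the highest mean over the 18 arrays, a choice that matters for 954 genes with more than 1. Genes whose highest group mean lay above the 30th percentile of all values (5.86 log2) were kept, 15711 in all. The 8512 probe sets without a single gene name that passed the same filter were fitted apart and only counted. Akr1b3 and Hspa1b have no probe set that names them alone and were not analysed here.

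limma 3.58.1 in R 4.3.3 fitted 1 model with a mean per group to all 18 arrays (12 residual degrees of freedom, 3.29 prior), and 9 contrasts were tested with moderated t tests and the Benjamini-Hochberg adjustment within each contrast. The contrasts are the hypertonic effect in WT, in WT with Torin1 and in KO cells, the Torin1 effect in each medium, KO against WT in each medium, and the difference of the hypertonic effect with Torin1 and with KO. A gene was called at an adjusted p below 0.05, and a second count asks for at least 2-fold as well. Lists of genes, 30 of 31 with at least 4 measured members, were written from general knowledge before the data were examined and tested with camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the residuals. Those with results given here cover osmolyte and NFAT5 targets, heat shock, p53, ATF4, endoplasmic reticulum chaperones, sterols, ribosome biogenesis, ribosomal proteins, lysosome, FOXO, DNA replication and mitosis. Further ones cover immediate early, NF-kB, interferon, actin and SRF, NRF2, circadian clock, matrix and fibroblast genes and markers of other cell types. Genes were named by a rule set before the data were examined: the 8 largest called increases and decreases of a contrast whose arrays do not overlap between the groups, without gene models and small RNA or multi-copy families, then the leading members of lists, and a set of osmolyte, chaperone and mTORC1 genes with Nfat5 in every contrast. The text leaves out some of these. Response scores are the mean change, signed by direction, of genes called in a contrast on arrays outside the arms compared, with an exact permutation test over number-matched values.

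The numbers 1, 2 and 4 in the titles were checked for pairing: after removing group means, arrays of the same number in different groups correlated with r from 0.156 to 0.847 over the genes, and 15 of 18 arrays had their closest array of another group under the same number. The labels do not say what the numbers stand for, so the fit has no block, and the same fit with the replicate number as a block was run for every result. Within groups arrays correlated at 0.968 to 0.997. Whether arrays of a group come from separate cultures is not stated, so p-values measure only the spread between these arrays. With 3 arrays per group, the number of arrays limits the precision.

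Alternatives chosen before the data were examined were no filter on dim genes or one at the 50th percentile, the mean of a gene's probe sets, quantile normalization again, centring each array on the median of its gene-level values, cyclic loess, a trended and robust prior, array weights, fits on only the groups of a contrast, the replicate block, isotonic KO array 1 counted as WT, each array left out in turn, and the estimated correlation. A block within each line, all arrays of number 4 left out, the replicate block with isotonic WT array 1 left out, the replicate block with an estimated correlation, and an exact test of the scores paired by number were added after the data had been seen, as were the score of the isotonic arrays on Torin1 genes, the comparison of number 4 with numbers 1 and 2, the comparison of marker list means within numbers, and the reading of imprinted and Dlk1-Dio3 genes. Simulated data of 15711 genes tested the fit for the hypertonic effect in WT. It recovered 82 of 100 genes changed by 1 log2 and 94 of 100 by 2. Of 178 calls 2 were false. Effects of array number may alter these rates.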

Results

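Gene levels were read on 18 arrays of mouse embryonic fibroblasts, in 6 groups of 3 arrays that carry the numbers 1, 2 and 4. A line with intact Nfat5 (WT) was kept in isotonic or hypertonic medium, with or without Torin1, an inhibitor of the kinase mTOR, given at 100 nM for 1 h beforehand. A line in which Nfat5 is knocked out (KO) was kept in isotonic or hypertonic medium without Torin1. Nfat5 encodes a transcription factor that turns on genes for the uptake and synthesis of organic osmolytes when the medium becomes hypertonic. The titles give 300 for isotonic and 500 for hypertonic medium, with no unit, and the time in hypertonic medium is not stated in the labels. Values are on the log2 scale, with array medians from 6.96 to 7.13 over all probe sets and 7.53 to 7.74 over gene-level values, and 15711 genes were tested. Changes below are log2 fold changes ± standard error from limma, with n = 3 arrays per group, and arrays are named by group and number.

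Nfat5 itself was read first, in every array. Its level in arrays 1, 2 and 4 was 10.13, 9.99 and 9.94 in isotonic WT cells, 10.77, 10.46 and 10.18 in hypertonic WT cells, 10.40, 10.03 and 10.12 in isotonic WT cells with Torin1, and 10.48, 10.36 and 10.01 in hypertonic WT cells with Torin1. In KO cells it was 9.83, 9.72 and 9.73 in isotonic and 10.13, 10.22 and 9.73 in hypertonic medium. The KO line differed from the WT line by -0.26 ± 0.16 in isotonic and -0.44 ± 0.16 in hypertonic medium, and neither difference passed (limma adjusted p = 0.367 and 0.0503). With the array numbers as a block the hypertonic difference passed (limma adjusted p = 0.00591) and the isotonic one did not (0.131). The hypertonic difference also passed without isotonic Torin1 array 1 (0.0487), hypertonic WT array 4 (0.0172), hypertonic Torin1 array 1 (0.0492), hypertonic Torin1 array 4 (0.0367) or hypertonic KO array 2 (0.0427). The probe set covers the whole transcript and cannot check a partial deletion, so these levels leave the genotype open. Isotonic KO array 1 is named KO in its title and wild-type in its genotype label, and it was kept with the KO group. On 5007 genes that differed between the lines in hypertonic medium, with 0 for the mean of the isotonic WT arrays and 1 for that of isotonic KO arrays 2 and 4, this array lay at 0.984, the other two isotonic KO arrays at 1.008 and 0.992, and the WT arrays between -0.202 and 0.103.

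**Figure D1:**
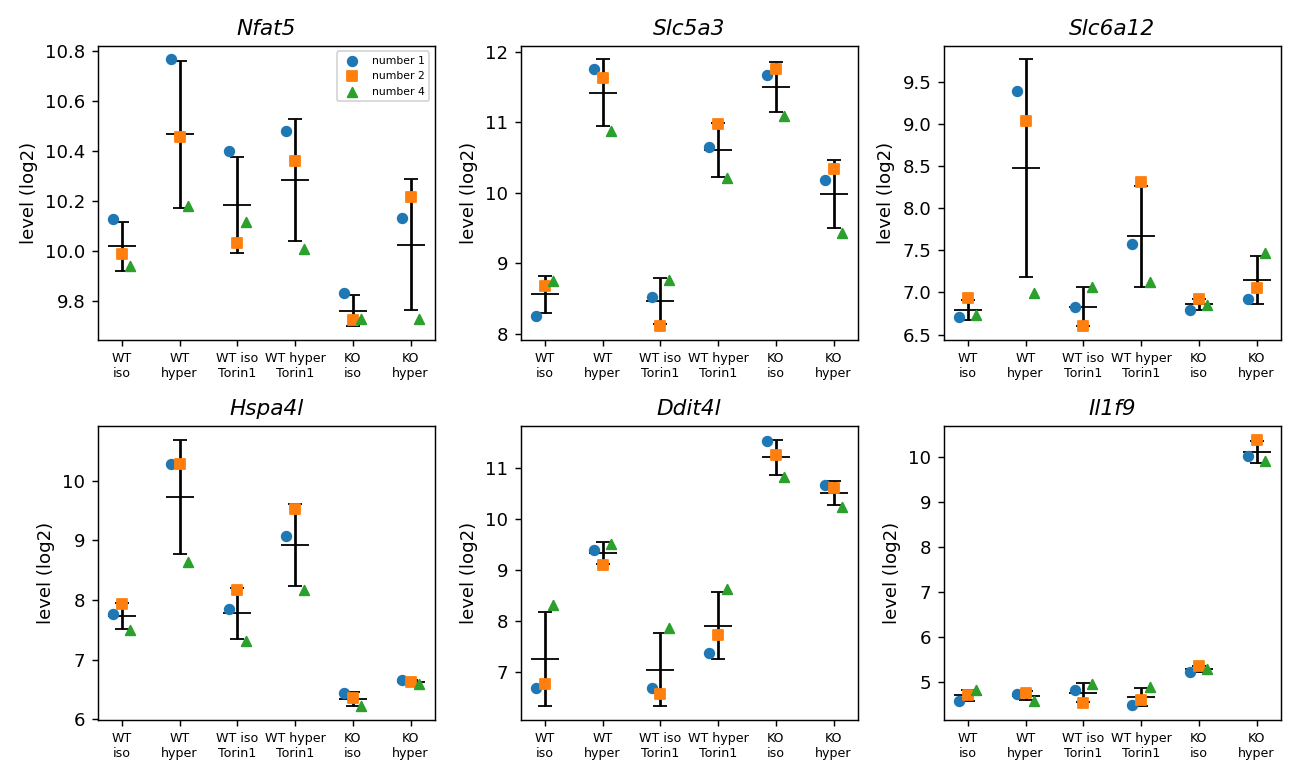
Levels (log2) of Nfat5, Slc5a3, Slc6a12, Hspa4l, Ddit4l and Il1f9 in each of the 18 arrays, by group, with markers for arrays 1, 2 and 4 and bars for mean ± SD of 3 arrays. Slc5a3 goes from 8.56 ± 0.27 to 11.42 ± 0.47 in WT cells and from 11.51 ± 0.36 to 9.99 ± 0.49 in KO cells.

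What hypertonic medium does to WT cells was asked by comparing hypertonic with isotonic WT arrays (n = 3 each). Slc5a3, the transporter that takes up the osmolyte myo-inositol, rose by 2.86 ± 0.29 (limma adjusted p = 0.000103), and Mrps6, a mitochondrial ribosomal protein gene whose interval overlaps that of Slc5a3, rose by 2.64 ± 0.29. Chaperone genes Hspa4l and Hspa1a, whose products refold proteins, rose by 2.00 ± 0.38 and 1.23 ± 0.12, and the linker histone gene H1f3 by 2.72 ± 0.35. Ddit4l, whose product holds back mTORC1, rose by 2.09 ± 0.42, and Gclc, which carries out the limiting step of glutathione synthesis, by 1.03 ± 0.19. Among the genes that fell were Bnip3, a receptor for the removal of mitochondria (-1.60 ± 0.33), Pdk1, a kinase that keeps pyruvate out of the citric acid cycle (-1.53 ± 0.33), and the clock gene Per3 (-1.42 ± 0.22). The betaine transporter gene Slc6a12 rose by 1.69 ± 0.44 (limma adjusted p = 0.0284). The call was lost without isotonic WT array 1 (0.083), isotonic WT array 2 (0.0616), isotonic WT array 4 (0.0725), hypertonic WT array 1 (0.151) or hypertonic WT array 2 (0.128). Changes of the taurine transporter gene Slc6a6 (-0.46 ± 0.25), of Nfat5 (0.45 ± 0.16) and of the mTORC1 inhibitor genes Ddit4 (1.06 ± 0.37) and Sesn1 (-0.10 ± 0.14) did not pass, though that of Nfat5 did with the array numbers as a block (limma adjusted p = 0.0154), and those of Nfat5 (0.0353) and Ddit4 (0.0252) did without hypertonic WT array 4. Counted as WT, isotonic KO array 1 brought the change of Ddit4l to 1.02 (limma adjusted p = 0.527).

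Of 11 measured osmolyte and NFAT5 target genes 5 rose, 0 fell and 6 did not pass (7 higher and 0 lower, adjusted over the list alone), with a median change of 0.77 (camera adjusted p = 0.00018, and adjusted p = 0.2 with an estimated correlation). Ribosome biogenesis genes, which build the ribosomal subunits, had 4 of 29 members higher, none lower and 25 not past (11 higher and 1 lower, adjusted over the list alone), among them the RNA polymerase I subunit gene Polr1a at 0.54 ± 0.11. The median was 0.38 (camera adjusted p = 4.78e-06, and adjusted p = 0.802 with an estimated correlation). Heat shock proteins and co-chaperones had 3 of 17 members higher and 14 not past (3 higher and 0 lower, adjusted over the list alone). The median was 0.26 (camera adjusted p = 0.0035, and adjusted p = 0.802 with an estimated correlation). Genes of mitosis, with 1 of 24 lower and 23 not past (0 higher and 1 lower, adjusted over the list alone), had a median of -0.34 (camera adjusted p = 0.000199, and adjusted p = 0.898 with an estimated correlation). Actin cytoskeleton genes, targets of the factor SRF, had 1 of 13 lower and 12 not past (0 higher and 1 lower, adjusted over the list alone), the tropomyosin gene Tpm2 at -0.63 ± 0.11. The median was -0.30 (camera adjusted p = 0.00151, and adjusted p = 0.802 with an estimated correlation). p53 target genes had 6 of 18 higher and 12 not past (8 higher and 0 lower, adjusted over the list alone). The median was 0.28 (camera adjusted p = 0.0035, and adjusted p = 0.802 with an estimated correlation). The p53 call was lost without isotonic WT array 1 (0.0551) or hypertonic WT array 4 (0.0536). Sterol genes had a median of -0.43 (camera adjusted p = 0.005, and adjusted p = 0.946 with an estimated correlation), with 1 member past over all genes and 1 adjusted over the list alone. The sterol call was lost without isotonic WT array 2 (0.0856) or hypertonic WT array 4 (0.0803). ATF4 targets had a median of 0.33 (camera adjusted p = 0.0395, and adjusted p = 0.946 with an estimated correlation), with 0 members past over all genes and 0 adjusted over the list alone. The ATF4 call was lost without isotonic WT array 1 (0.689), isotonic WT array 4 (0.191), hypertonic WT array 1 (0.245) or hypertonic WT array 2 (0.0591). List medians moved with single arrays. That of the osmolyte genes was 1.25 without isotonic WT array 2 and 1.33 without hypertonic WT array 4, and that of the p53 targets 0.42 without isotonic WT array 2 and 0.43 without isotonic WT array 4. For ATF4 targets it was -0.01, 0.78 and 0.20 without isotonic WT arrays 1, 2 and 4, 0.16 without hypertonic WT array 1 and 0.62 without hypertonic WT array 4. For sterol genes it was -0.65 without isotonic WT array 1 and -0.28 without hypertonic WT array 4, where the actin median was -0.18. Tpm2 did not pass with isotonic KO array 1 counted as WT (-0.46, limma adjusted p = 0.064).

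Hypertonic medium raised 619 and lowered 676 of the 15711 genes in WT cells, 80 and 68 of them at least 2-fold, and the counts were 1162 and 1198 with the array numbers as a block. The count of 1295 genes was 734 without isotonic WT array 1, 781 without isotonic WT array 2, 534 without hypertonic WT array 1 and 635 without hypertonic WT array 2.

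The same comparison was made in the KO line (n = 3 each). Il1f9, a cytokine of the interleukin-1 family, rose by 4.84 ± 0.14 (limma adjusted p = 7.16e-12), the chemokine gene Ccl3 by 2.93 ± 0.60 (1.82 without hypertonic KO array 4), and Ptgs2, which makes prostaglandins, by 2.22 ± 0.27. Slc5a3 fell by 1.52 ± 0.29 (limma adjusted p = 0.0009), and the mTORC1 inhibitor gene Sesn1 fell by 0.88 ± 0.14. The glutathione synthesis genes Gclc and Gclm rose by 1.99 ± 0.19 and 1.59 ± 0.17, and the heme oxygenase gene Hmox1 by 1.55 ± 0.16. Slc6a12 (0.29 ± 0.44), Slc6a6 (-0.60 ± 0.25) and Ddit4l (-0.70 ± 0.42) did not pass in KO cells, though Slc6a6 did with the array numbers as a block (limma adjusted p = 0.0434) and without isotonic KO array 4 (0.0154) or hypertonic KO array 2 (0.0312). With isotonic KO array 1 as WT the fall of Slc5a3 did not pass (-1.44, limma adjusted p = 0.184).

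Sterol genes, which make and take up cholesterol, had 10 of 20 measured members lower and 10 not past (0 higher and 12 lower, adjusted over the list alone), with the synthesis genes Dhcr7 at -1.71 ± 0.22, Mvk at -1.62 ± 0.23 and Hmgcs1 at -1.40 ± 0.30. The median was -0.82 (camera adjusted p = 0.00026, and adjusted p = 0.996 with an estimated correlation). Of 17 heat shock genes 8 rose and 9 did not pass (9 higher and 0 lower, adjusted over the list alone), among them Hsph1 (0.70 ± 0.19), Dnajb1 (0.62 ± 0.15) and the transcription factor gene Hsf2 (0.90 ± 0.11). The median was 0.33 (camera adjusted p = 0.00389, and adjusted p = 0.95 with an estimated correlation). p53 targets counted 7 of 18 higher and 11 not past (7 higher and 0 lower, adjusted over the list alone), with Mdm2, which breaks down p53, at 1.20 ± 0.11 and the exonuclease gene Aen at 1.36 ± 0.19. The median was 0.45 (camera adjusted p = 0.00451, and adjusted p = 0.95 with an estimated correlation). Ribosome biogenesis genes counted 11 higher, 1 lower and 17 not past (12 higher and 1 lower, adjusted over the list alone), the nucleolar gene Gnl3 at 0.93 ± 0.20 and Bysl at 0.86 ± 0.22. The median was 0.40 (camera adjusted p = 0.00108, and adjusted p = 0.996 with an estimated correlation). Immediate early genes, which answer stimuli within minutes, had 8 of 20 higher and 12 not past (8 higher and 0 lower, adjusted over the list alone), Klf4 at 1.74 ± 0.14 and Zfp36, which destabilizes cytokine messages, at 1.19 ± 0.15. The median was 0.52 (camera adjusted p = 0.00451, and adjusted p = 0.95 with an estimated correlation). NRF2 targets had 5 of 14 higher and 9 not past (5 higher and 0 lower, adjusted over the list alone). The median was 0.62 (camera adjusted p = 0.0068, and adjusted p = 0.95 with an estimated correlation). FOXO targets had 8 of 21 higher, 1 lower and 12 not past (9 higher and 1 lower, adjusted over the list alone). The median was 0.34 (camera adjusted p = 0.0123, and adjusted p = 0.95 with an estimated correlation). The FOXO call was lost without isotonic KO array 2 (0.0584) or hypertonic KO array 4 (0.0557). With the arrays centred on their medians the immediate early, NRF2 and FOXO lists had a camera adjusted p of 0.0524 each. Osmolyte genes did not pass as a list, with 2 higher, 1 lower and 8 not past (2 higher and 1 lower, adjusted over the list alone), and mitosis genes passed with the array numbers as a block (camera adjusted p = 0.0468) but not without (0.106). The sterol median was -0.53 without hypertonic KO array 4, and Hsph1 and Hmgcs1 did not pass with isotonic KO array 1 as WT (limma adjusted p = 0.0642 and 0.0807).

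In KO cells 2030 genes rose and 2704 fell, 207 and 523 of them at least 2-fold. The share of higher genes among those called was 42.9%, and 68.9% with each array centred on the median of its gene-level values, which moves the median change of all genes to 0.17.

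Whether the response to hypertonic medium differs between the lines was tested as the KO change minus the WT change (n = 3 per group). The Slc5a3 response differed by -4.38 ± 0.41 (limma adjusted p = 5.67e-05), that of Mrps6 by -3.05 ± 0.41, and that of Ddit4l by -2.79 ± 0.60. Il1f9 (4.85 ± 0.19), the AMPK-related kinase gene Nuak2 (1.99 ± 0.29), the cytokine gene Tnfsf18 (1.67 ± 0.34) and Gclm (1.38 ± 0.24) responded more strongly upward in KO cells. Decoy receptor genes of the TNF family, Tnfrsf22 and Tnfrsf23, differed by -2.94 ± 0.51 and -2.66 ± 0.44, and Hspa1a by -0.83 ± 0.17. The difference for Sesn1 was -0.78 ± 0.19 (limma adjusted p = 0.0194), a call lost without isotonic WT array 2 (0.0527) or hypertonic KO array 2 (0.0563). Of the osmolyte genes 3 had a lower response in KO cells and 8 did not pass (0 higher and 4 lower, adjusted over the list alone). The median was -0.83 (camera adjusted p = 0.0209, and adjusted p = 0.676 with an estimated correlation). The osmolyte call was lost without hypertonic WT array 1 (0.0504). FOXO targets had 2 members with a higher response and 19 not past (2 higher and 0 lower, adjusted over the list alone), among them the autophagy kinase gene Ulk1 at 0.78 ± 0.16 and Ccng2 at 0.69 ± 0.16. The median was 0.35 (camera adjusted p = 0.0113, and adjusted p = 0.807 with an estimated correlation). In the circadian clock list 3 of 15 responded higher and 12 did not pass (3 higher and 0 lower, adjusted over the list alone), the clock repressor gene Cry1 at 1.14 ± 0.20. The median was 0.30 (camera adjusted p = 0.0205, and adjusted p = 0.943 with an estimated correlation). The clock call was lost without hypertonic WT array 4 (0.0619). NRF2 targets counted 4 of 14 (5 adjusted over the list alone). The median was 0.31 (camera adjusted p = 0.0205, and adjusted p = 0.676 with an estimated correlation). The NRF2 call was lost without hypertonic KO array 4 (0.0554). Immediate early genes counted 2 of 20 (2 adjusted over the list alone). The median was 0.28 (camera adjusted p = 0.03, and adjusted p = 0.943 with an estimated correlation). The immediate early call was lost without isotonic WT array 2 (0.0604), hypertonic WT array 4 (0.161), isotonic KO array 1 (0.0891) or hypertonic KO array 4 (0.0525). With the arrays centred on their medians the NRF2 and clock lists had a camera adjusted p of 0.0983 each and the immediate early list one of 0.204. Without the arrays of number 4 the NRF2 list had one of 0.0882. Counting isotonic KO array 1 as WT, the FOXO list had one of 0.0553 and the immediate early list one of 0.533, while Nuak2 (1.28), Mrps6 (-2.26), Ddit4l (-1.55) and Sesn1 (-0.69) did not pass (limma adjusted p = 0.483, 0.11, 0.641 and 0.0733). The clock median was 0.51 without hypertonic WT array 1, 0.17 without hypertonic WT array 4, 0.19 without hypertonic KO array 2 and 0.46 without hypertonic KO array 4. The immediate early median was 0.13 without hypertonic WT array 4, 0.15 without isotonic KO array 1 and 0.18 without hypertonic KO array 2. With the array numbers as a block the sterol and lysosome lists passed (camera adjusted p = 0.0234 and 0.0481), and without it they did not (0.0557 and 0.0813).

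The response was higher in KO cells for 526 genes and lower for 966, 91 and 295 at least 2-fold, and for 871 and 1409 with the array numbers as a block. The share of higher calls was 35.2%, against 47.9% after quantile normalization of the values and 69.8% with the arrays centred on their medians. The count of 1492 genes was 832 without hypertonic WT array 2, 992 without hypertonic KO array 1 and 908 without hypertonic KO array 2.

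**Figure D2:**
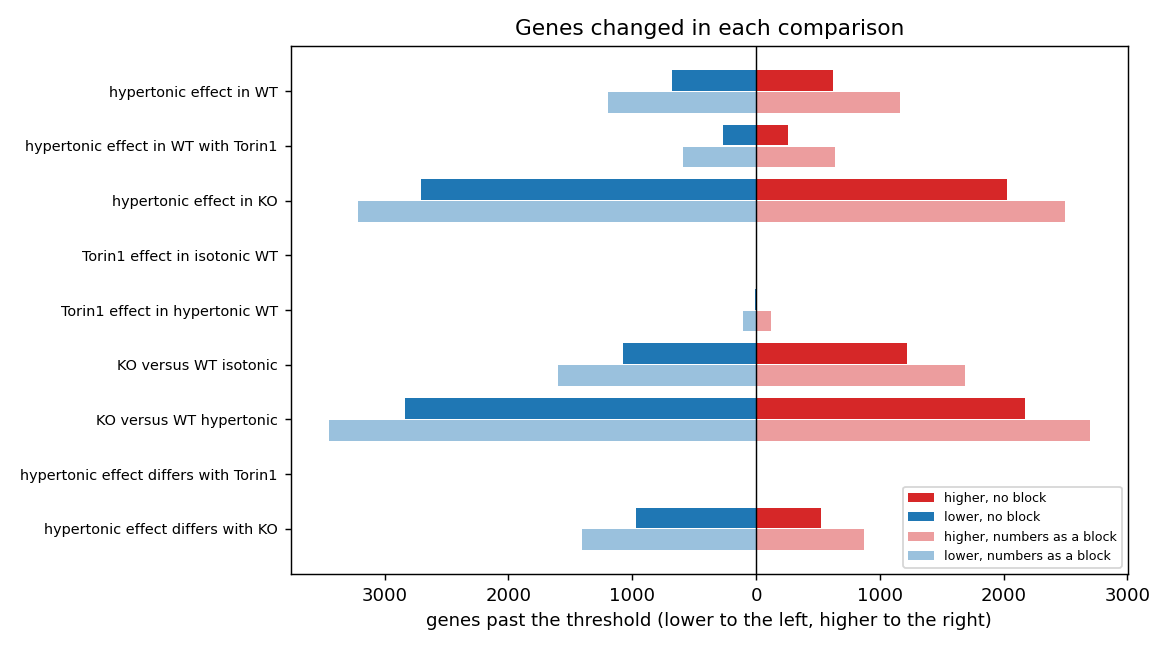
Genes higher and lower (bars, number of genes at adjusted p below 0.05) in each comparison, without a block and with the array numbers as a block. The hypertonic effect counts 1295 genes in WT cells, 530 in WT cells with Torin1 and 4734 in KO cells without the block.

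The effect of hypertonic medium was also measured in WT cells pretreated with Torin1 (n = 3 each). Slc5a3 rose by 2.15 ± 0.29 (limma adjusted p = 0.00117), Mrps6 by 2.34 ± 0.29 and H1f3 by 2.03 ± 0.35. P4ha3, a subunit of the enzyme that hydroxylates collagen, fell by 1.46 ± 0.14, and Chid1, a chitinase-like gene, fell by 1.23 ± 0.18. Slc6a12 (0.84 ± 0.44) and Ddit4l (0.87 ± 0.42) did not pass with Torin1. Actin and SRF target genes had 3 of 13 lower and 10 not past (0 higher and 4 lower, adjusted over the list alone), with Tpm2 at -0.65 ± 0.11 and the smooth muscle actin gene Acta2 at -0.43 ± 0.07. The median was -0.38 (camera adjusted p = 3.25e-07, and adjusted p = 0.676 with an estimated correlation). Ribosome biogenesis genes had 1 of 29 higher and 28 not past (1 higher and 0 lower, adjusted over the list alone), Polr1a at 0.63 ± 0.11. The median was 0.40 (camera adjusted p = 3.86e-05, and adjusted p = 0.984 with an estimated correlation). Osmolyte genes counted 1 higher and 10 not past (5 higher and 2 lower, adjusted over the list alone). The median was 0.40 (camera adjusted p = 0.0316, and adjusted p = 0.885 with an estimated correlation). The osmolyte call was lost without isotonic Torin1 array 1 (0.055), hypertonic Torin1 array 1 (0.108) or hypertonic Torin1 array 2 (0.0688). The mitosis list (median -0.30, camera adjusted p = 0.000411, and adjusted p = 0.984 with an estimated correlation) and the p53 list (median 0.27, camera adjusted p = 0.0316, and adjusted p = 0.984 with an estimated correlation) had no member past over all genes or adjusted over the list alone. The mitosis call was lost without isotonic Torin1 array 1 (0.088) or isotonic Torin1 array 2 (0.0699), and the p53 call without isotonic Torin1 array 1 (0.247), hypertonic Torin1 array 2 (0.059) or hypertonic Torin1 array 4 (0.184). ATF4 targets passed with the array numbers as a block (camera adjusted p = 0.0289) but not without (0.0955). The actin median was -0.18 without hypertonic Torin1 array 4, the ribosome biogenesis and p53 medians 0.25 and 0.18 without hypertonic Torin1 array 2, and the mitosis median -0.12, -0.19 and -0.54 without isotonic Torin1 arrays 1, 2 and 4. Counting isotonic KO array 1, of neither group here, as WT left the Slc5a3 change at 2.15 (limma adjusted p = 0.112).

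With Torin1 hypertonic medium raised 260 and lowered 270 genes, 46 and 25 at least 2-fold, and 641 and 594 with the array numbers as a block. The count of 530 genes was 183 without isotonic Torin1 array 1, 270 without isotonic Torin1 array 2, 291 without isotonic Torin1 array 4 and 161 without hypertonic Torin1 array 2.

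What Torin1 does in isotonic medium was asked by comparing isotonic WT arrays with and without it (n = 3 each). No gene passed limma over all genes, and the largest changes included the mitochondrial folate enzyme gene Mthfd2 (-1.46 ± 0.39) and the cystine transporter gene Slc7a11 (-1.69 ± 0.59), each with a limma adjusted p of 1. As a list the ATF4 and amino acid response genes, 25 of 26 of them on the lower side, passed. The median was -0.66 (camera adjusted p = 2.7e-18, and adjusted p = 0.219 with an estimated correlation), and 8 members were lower adjusted over the list alone. Endoplasmic reticulum chaperone genes had a median of -0.38 (camera adjusted p = 1.86e-12, and adjusted p = 0.219 with an estimated correlation), 8 of 15 lower adjusted over the list alone, sterol genes one of -0.47 (camera adjusted p = 3.25e-14, and adjusted p = 0.255 with an estimated correlation), and DNA replication genes one of -0.41 (camera adjusted p = 8.54e-15, and adjusted p = 0.219 with an estimated correlation), with 0 and 0 lower adjusted over the list alone. FOXO targets had a median of 0.18 (camera adjusted p = 5.06e-05, and adjusted p = 0.219 with an estimated correlation), with 0 higher adjusted over the list alone, and no list had a member past over all genes. The mean of the ATF4 list, centred over all arrays, was -0.44, 0.79 and -0.02 in untreated arrays 1, 2 and 4 and -0.50, -0.50 and -0.71 in the Torin1 arrays. Its median change was -0.29 without isotonic WT array 2, where that of the FOXO targets was 0.09. The chaperone median was -0.25 without isotonic WT array 4, and the sterol and DNA replication medians were -0.31 and -0.25 without isotonic Torin1 array 4. These are the 5 of 11 lists called whose calls stayed whichever array was left out, and ribosome biogenesis passed with the array numbers as a block (camera adjusted p = 0.0493) but not without (0.0722). At an unadjusted p below 0.05 limma had 470 genes, where 786 are expected by chance. The count was 788 with the array numbers as a block, and a count under chance is no evidence against an effect. On a score of 200 genes picked on the hypertonic arrays, with 0 for isotonic WT arrays 2 and 4 and 1 for isotonic Torin1 arrays 2 and 4, the untreated isotonic WT array 1 lay at 0.959 and isotonic Torin1 array 1 at 0.989. Without isotonic WT array 1 limma called 25 genes, and 295 (48 higher, 247 lower) with the array numbers as a block as well.

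**Figure D3:**
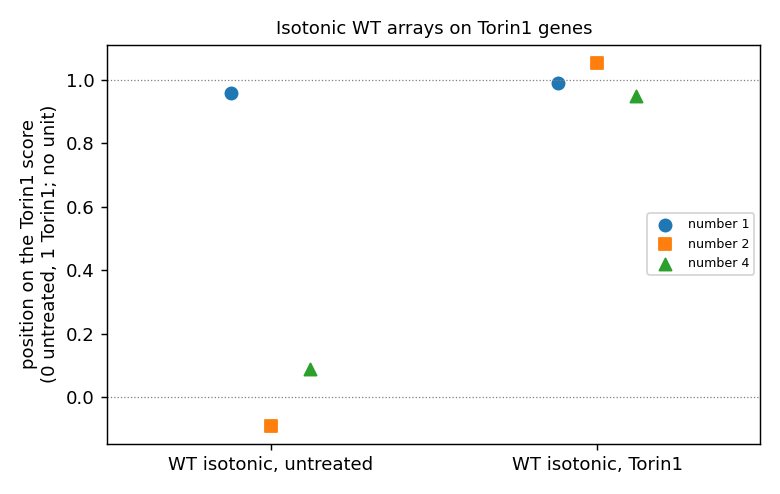
Position of each isotonic WT array on the Torin1 score (vertical axis without unit, 0 for untreated arrays 2 and 4, 1 for Torin1 arrays 2 and 4), untreated arrays beside Torin1 arrays, points being single arrays. Untreated array 1 lies at 0.959, among Torin1 arrays at 0.947 to 1.053.

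The effect of Torin1 in hypertonic medium compared hypertonic WT arrays with and without it (n = 3 each). Hspa1a, the inducible HSP70 gene, fell by 0.92 ± 0.12 (limma adjusted p = 0.0147). The call was lost without hypertonic WT array 1 (0.0878), hypertonic WT array 2 (0.0713) or hypertonic Torin1 array 2 (0.084). The glutamate transporter gene Slc1a3 fell by 1.06 ± 0.14 (limma adjusted p = 0.0154). The call was lost without hypertonic WT array 1 (0.0878), hypertonic WT array 2 (0.0713), hypertonic Torin1 array 1 (0.0847) or hypertonic Torin1 array 2 (0.102). Slc5a3 (-0.81 ± 0.29), Ddit4l (-1.43 ± 0.42) and the arginine transporter gene Slc7a1 (-1.24 ± 0.29) did not pass, though Slc7a1 did with the array numbers as a block (limma adjusted p = 0.0196). ATF4 targets had a median of -0.84 (camera adjusted p = 5.62e-11, and adjusted p = 0.474 with an estimated correlation), none of 26 past over all genes and 10 lower adjusted over the list alone. Osmolyte genes had 1 lower and 10 not past (1 lower adjusted over the list alone). The median was -0.51 (camera adjusted p = 0.000508, and adjusted p = 0.372 with an estimated correlation). Heat shock genes (median -0.22, camera adjusted p = 8.79e-05, and adjusted p = 0.474 with an estimated correlation) had 3 of 17, p53 targets (median -0.33, camera adjusted p = 0.0012, and adjusted p = 0.478 with an estimated correlation) 7 of 18, and endoplasmic reticulum chaperones (median -0.22, camera adjusted p = 9.28e-05, and adjusted p = 0.478 with an estimated correlation) 3 of 15 lower adjusted over the list alone, and none past over all genes. FOXO targets lay the other way. The median was 0.20 (camera adjusted p = 0.000499, and adjusted p = 0.474 with an estimated correlation), none of 21 past over all genes and 7 higher adjusted over the list alone. The osmolyte median was -1.02 without hypertonic WT array 4 and -0.88 without hypertonic Torin1 array 2, and the p53 median -0.15 without hypertonic WT array 4 and -0.17 without hypertonic Torin1 array 1. These are the 6 of 10 lists called whose calls stayed whichever array was left out.

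In hypertonic medium Torin1 raised 9 and lowered 9 genes, 0 and 2 at least 2-fold, and 118 and 102 with the array numbers as a block. The count of 18 genes was 0 without hypertonic WT array 1, hypertonic WT array 2 or hypertonic Torin1 array 2, and 1 without hypertonic Torin1 array 1. It was 2 to 9 without 9 other arrays, 119 without hypertonic WT array 4 and 148 without isotonic WT array 1.

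Whether Torin1 changes the response to hypertonic medium was tested as the change with Torin1 minus the change without it. No gene passed limma over all genes, with 317 at an unadjusted p below 0.05, where 786 are expected by chance. The count was 555 with the array numbers as a block, and is likewise no evidence against an effect. The difference for Slc5a3 was -0.72 ± 0.41, for Hspa1a -0.82 ± 0.17 and for Ddit4l -1.22 ± 0.60, each with a limma adjusted p of 1. As a list the osmolyte genes had a median of -0.38 (camera adjusted p = 0.000132, and adjusted p = 0.182 with an estimated correlation), none past over all genes and 1 lower adjusted over the list alone. That median was -0.78 without isotonic WT array 2, -0.93 without hypertonic WT array 4, -0.74 without hypertonic Torin1 array 1 and -0.79 without hypertonic Torin1 array 2. Among the arrays, the centred mean of the list was 1.17, 1.09 and 0.31 in hypertonic WT arrays 1, 2 and 4 and 0.54, 0.72 and -0.04 in hypertonic Torin1 arrays. Sterol genes, among them Cyp51 (1.10 ± 0.55) of cholesterol synthesis and the sterol sensor gene Insig1 (1.01 ± 0.53), had a median of 0.44 (camera adjusted p = 1.16e-06, and adjusted p = 0.966 with an estimated correlation), none past over all genes and 0 adjusted over the list alone, and the median was 0.27 without isotonic Torin1 array 4 and 0.66 without hypertonic Torin1 array 4. DNA replication genes had a median of 0.25 (camera adjusted p = 0.00629, and adjusted p = 0.966 with an estimated correlation), with no member past over all genes and 0 adjusted over the list alone. The DNA replication call was lost without isotonic WT array 2 (0.0849), isotonic WT array 4 (0.282), isotonic Torin1 array 4 (0.396), hypertonic WT array 4 (0.219) or hypertonic Torin1 array 1 (0.468). Its median was 0.46 without isotonic WT array 1, 0.41 and 0.09 without isotonic Torin1 arrays 1 and 4, 0.12 without hypertonic WT array 4, and 0.11 and 0.44 without hypertonic Torin1 arrays 1 and 4. Between WT cells without and with Torin1, 199 genes rose in both and 203 fell in both, where 10.2 and 11.6 would be shared by independent lists, and no gene was called in opposite directions. Over the 4734 genes called in KO cells, the mean response was 0.21 ± 0.10 (SD) without and 0.14 ± 0.02 with Torin1, n = 3, a difference of -0.08 (exact permutation p = 0.2). The differences of the number-matched responses were -0.21, -0.01 and -0.01 for numbers 1, 2 and 4 (exact paired p = 0.25, the smallest that 3 pairs can give). The score difference was -0.02 without isotonic WT array 1 and -0.02 without hypertonic WT array 1.

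How the lines differ without osmotic stress was asked by comparing isotonic KO with isotonic WT arrays (n = 3 each), with 1 line per genotype. Efemp1, which encodes a fibulin, was higher in KO cells by 6.66 ± 0.25 (limma adjusted p = 3.22e-11), and the genes of the collagen-binding proteins Prelp and Fmod by 5.85 ± 0.26 and 5.25 ± 0.22. The Wnt antagonist gene Sfrp2 was higher by 5.77 ± 0.23, and the growth factor gene Hgf by 5.57 ± 0.81. Lower in KO cells were Grem1, which blocks bone morphogenetic proteins (-5.79 ± 0.28), and the transcription factor genes Pax8 (-5.45 ± 0.17), Tfap2a (-5.31 ± 0.31) and Sox11 (-4.74 ± 0.13). Already in isotonic medium Slc5a3 was higher in KO cells by 2.94 ± 0.29 and Ddit4l by 3.96 ± 0.42, while Slc6a6 (-2.33 ± 0.25) and the ubiquitin ligase gene Rnf128 (-1.98 ± 0.24) were lower.

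Sterol genes had 12 of 20 higher in isotonic KO cells and 8 not past (19 higher and 0 lower, adjusted over the list alone), with Tm7sf2 at 1.59 ± 0.34 and Mvd at 1.26 ± 0.29. The median was 1.01 (camera adjusted p = 1.53e-07, and adjusted p = 0.608 with an estimated correlation). Actin and SRF target genes had 8 of 13 lower and 5 not past (0 higher and 8 lower, adjusted over the list alone), the calponin gene Cnn1 at -4.49 ± 0.24 and the actin gene Actg2 at -3.46 ± 0.22. The median was -0.51 (camera adjusted p = 1.53e-07, and adjusted p = 0.223 with an estimated correlation). Adipocyte marker genes had 5 of 6 higher and 1 not past (5 higher and 0 lower, adjusted over the list alone), the adipocyte regulator Pparg at 3.99 ± 0.32 and the lipase gene Lpl at 3.43 ± 0.13. The median was 1.78 (camera adjusted p = 3.01e-07, and adjusted p = 0.223 with an estimated correlation). Cartilage and bone markers did not pass as a list (camera adjusted p = 0.0981), with 2 of 5 higher, Sox9 at 2.59 ± 0.36 and Sp7 at 1.73 ± 0.21, and 3 not past (3 higher and 1 lower, adjusted over the list alone). Nor did another marker list pass, though the endothelial receptor gene Tek (2.05 ± 0.39), the cadherin gene Cdh1 (1.72 ± 0.22), the muscle filament gene Des (0.60 ± 0.14) and the macrophage lysozyme gene Lyz2 (0.69 ± 0.19) were higher and the neural filament gene Nes lower (-2.91 ± 0.52). Of these calls that of Lyz2 was lost without isotonic WT array 1 (0.105), isotonic KO array 2 (0.0746) or isotonic KO array 4 (0.0807). NRF2 targets had 5 of 14 higher and 9 not past (5 higher and 0 lower, adjusted over the list alone), the glutathione transferase gene Gsta4 at 3.38 ± 0.49 and Nqo1 at 1.34 ± 0.20. The median was 0.33 (camera adjusted p = 0.00283, and adjusted p = 0.223 with an estimated correlation). Immediate early genes had 6 of 20 lower and 14 not past (0 higher and 6 lower, adjusted over the list alone), the phosphatase gene Dusp1 at -1.58 ± 0.22 and Klf4 at -1.38 ± 0.14. The median was -0.26 (camera adjusted p = 0.00283, and adjusted p = 0.608 with an estimated correlation). NF-kB genes had 4 of 19 lower (4 adjusted over the list alone), Ptgs2 at -2.60 ± 0.27. The median was -0.49 (camera adjusted p = 0.0267, and adjusted p = 0.815 with an estimated correlation), with 0.119 once the array numbers are a block. The NF-kB call was lost without isotonic WT array 4 (0.285), isotonic KO array 1 (0.285) or isotonic KO array 2 (0.121). Its median was -0.24 without isotonic WT array 4 and -0.22, -0.30 and -0.84 without isotonic KO arrays 1, 2 and 4. Without isotonic KO array 4 the NRF2 median was 0.50 and the immediate early one -0.44. Cytosolic ribosomal protein genes had none of 19 past over all genes and 0 higher adjusted over the list alone. The median was 0.20 (camera adjusted p = 0.00773, and adjusted p = 0.815 with an estimated correlation). The ribosomal protein call was lost without isotonic WT array 4 (0.114), without the arrays of number 4 (0.199) and with array weights (0.0959). Extracellular matrix and fibroblast markers did not pass as a list, with 7 of 22 higher, the surface antigen gene Thy1 at 3.88 ± 0.17 among them, 2 lower and 13 not past (8 higher and 2 lower, adjusted over the list alone).

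In isotonic medium 1223 genes were higher and 1075 lower in KO cells, 462 and 400 at least 2-fold. Counting isotonic KO array 1 as WT, which by its position mixes the lines, left 0 genes past (limma, 2216 at unadjusted p below 0.05).

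The lines were also compared in hypertonic medium (n = 3 each), the condition in which NFAT5 is known to act. Slc5a3 was lower in KO cells (-1.44 ± 0.29, limma adjusted p = 0.0013), as were Slc6a6 (-2.48 ± 0.25), Hspa4l (-3.11 ± 0.38), the water channel gene Aqp1 (-2.70 ± 0.54) and Sesn1 (-0.64 ± 0.14). Il1f9 was higher by 5.43 ± 0.14, Efemp1 by 6.79 ± 0.25 and the vasopressin receptor gene Avpr1a by 5.71 ± 0.31. Slc6a12 differed by -1.33 ± 0.44 (limma adjusted p = 0.0309). The call was lost without hypertonic WT array 1 (0.147), hypertonic WT array 2 (0.132), hypertonic KO array 1 (0.0977) or hypertonic KO array 2 (0.0832). The difference of Slc6a12 was -0.87 without hypertonic WT array 1 and -2.07 without hypertonic WT array 4. Ddit4l was higher by 1.17 ± 0.42 (limma adjusted p = 0.045). The call was lost without isotonic Torin1 array 1 (0.051), hypertonic WT array 1 (0.0789), hypertonic WT array 2 (0.129), hypertonic WT array 4 (0.0678), hypertonic Torin1 array 2 (0.0534), isotonic KO array 1 (0.0513), isotonic KO array 2 (0.0559), hypertonic KO array 1 (0.122), hypertonic KO array 2 (0.112) or hypertonic KO array 4 (0.0531). With isotonic KO array 1 as WT neither Slc5a3 nor Ddit4l passed (limma adjusted p = 0.11 and 0.35).

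Of the 11 osmolyte genes 8 were lower in hypertonic KO than hypertonic WT cells, 0 higher and 3 not past (0 higher and 9 lower, adjusted over the list alone). The median was -1.33 (camera adjusted p = 0.00045, and adjusted p = 0.166 with an estimated correlation). NRF2 targets had 8 of 14 higher and 6 not past (10 higher and 0 lower, adjusted over the list alone), Gsta4 at 3.58 ± 0.49, Hmox1 at 2.30 ± 0.16 and Osgin1 at 2.16 ± 0.22. The median was 1.01 (camera adjusted p = 2.76e-05, and adjusted p = 0.0977 with an estimated correlation). Actin and SRF targets had 7 of 13 lower and 6 not past (0 higher and 8 lower, adjusted over the list alone), Cnn1 at -3.54 ± 0.24. The median was -0.37 (camera adjusted p = 0.000314, and adjusted p = 0.608 with an estimated correlation). Adipocyte markers had 5 of 6 higher and 1 not past (5 higher and 0 lower, adjusted over the list alone), Lpl at 4.95 ± 0.13 and Pparg at 4.01 ± 0.32. The median was 1.66 (camera adjusted p = 2.76e-05, and adjusted p = 0.187 with an estimated correlation). No other cell type marker list passed, but single markers did, with Tek (2.44 ± 0.39), Sox9 (1.19 ± 0.36), Cdh1 (0.79 ± 0.22) and Lyz2 (0.59 ± 0.19) higher and Nes (-2.53 ± 0.52) and the macrophage receptor gene Csf1r (-1.36 ± 0.24) lower. The Sox9 call was lost without hypertonic WT array 2 (0.0713), hypertonic KO array 1 (0.0672) or hypertonic KO array 2 (0.0998), that of Cdh1 without hypertonic KO array 2 (0.0595), and that of Lyz2, whose level lay near the filter level, without hypertonic WT array 1 (0.0666), hypertonic WT array 2 (0.0617), hypertonic KO array 1 (0.0862) or hypertonic KO array 2 (0.0749). Ribosomal protein genes had 5 of 19 higher and 14 not past (5 higher and 0 lower, adjusted over the list alone). The median was 0.21 (camera adjusted p = 0.0301, and adjusted p = 0.948 with an estimated correlation). The ribosomal protein call was lost without hypertonic WT array 4 (0.103) or hypertonic KO array 4 (0.136), and without the arrays of number 4 (0.377). It was also lost with cyclic loess (0.188) and with array weights (0.225). The osmolyte median was -0.87 without hypertonic WT array 1, and the ribosomal protein median 0.14 without hypertonic WT array 4. With isotonic KO array 1 as WT neither Cdh1 nor Sox9 passed (limma adjusted p = 0.202 and 0.192). With the array numbers as a block the p53 (0.0438, against 0.0559), sterol (0.0283, against 0.0559) and circadian (0.0404, against 0.0559) lists passed by camera as well.

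In hypertonic medium 2173 genes were higher and 2834 lower in KO cells, 467 and 748 at least 2-fold, a share of higher calls of 43.4% and of 69.8% with the arrays centred on their medians. Genes higher in KO cells in both media numbered 776 and lower in both 705, against 169 and 194 for independent lists.

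How much of the response to hypertonic medium the lines share was asked gene by gene, and a score was set beside it. Genes that rose in both lines numbered 272 and genes that fell in both 493, against 80 and 116 for independent lists, with a correlation of 0.464 over all genes. Per3 fell in WT (-1.42 ± 0.22) and in KO cells (-1.31 ± 0.22), Gclc rose in both (1.03 ± 0.19 and 1.99 ± 0.19), and so did the prolactin family gene Prl2c5 (2.89 ± 0.43 and 2.27 ± 0.43). In opposite directions, 32 genes rose in WT and fell in KO cells, among them Slc5a3 and the growth factor gene Fgf10 (1.00 and -1.27), and 11 fell in WT and rose in KO cells, among them Nuak2 (-0.98 and 1.01) and Fnip1 (-0.38 and 0.64), a partner of folliculin. Over the 530 genes called in WT cells with Torin1, the mean response was 0.68 ± 0.08 (SD) in WT and 0.45 ± 0.09 in KO cells, n = 3 each, a difference of -0.23 (exact permutation p = 0.1, the smallest that 3 against 3 values can give). These genes were picked in the WT line, so a larger score in WT cells would follow from the choice alone, and the difference does not measure how much the lines share. For numbers 1, 2 and 4 the differences were -0.34, -0.29 and -0.06 (exact paired p = 0.25, the smallest that 3 pairs can give). Without hypertonic WT array 1 the score difference was -0.13, and without isotonic Torin1 array 1 it was -0.34.

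The array of number 4 was set against numbers 1 and 2 in every group, after the values had been seen. Over the 4 WT conditions Ifit1, an interferon-induced gene, lay 5.19 ± 0.43 (SD) higher in number 4 than in numbers 1 and 2, and Usp18, which restrains interferon signalling, 5.11 ± 0.42. The acute-phase genes Lcn2 and Saa3 lay 7.13 ± 0.15 and 6.08 ± 0.61 higher, and the cytokine gene Il6 4.63 ± 1.16. In the 2 KO conditions the means were 0.50 for Ifit1 and 0.44 for Usp18, but 5.38 for Lcn2 and 7.60 for Saa3. The 13 interferon response genes averaged 3.07 ± 0.54 (SD) in WT, from 2.42 to 3.69, and 0.68 and 0.12 in isotonic and hypertonic KO cells (exact permutation p = 0.0667, the smallest possible for 4 against 2 conditions). NF-kB and inflammatory genes averaged 1.78 ± 0.49 in WT and 2.12 and 1.61 in KO cells. Of the cell type marker lists, the 5 neural and glial markers averaged -0.79 ± 0.13 (SD) in WT and -0.60 and -0.73 in KO cells, and the 6 adipocyte markers 0.14 ± 0.10 in WT and -0.78 and -0.57 in KO cells. The endothelial markers averaged 0.01 ± 0.12 in WT and -0.40 and -0.30 in KO cells, the matrix and fibroblast markers -0.05 ± 0.02 and -0.22 and -0.30, and the epithelial markers -0.07 ± 0.20 and -0.38 and -0.16. Macrophage markers averaged 0.00 ± 0.15 in WT and 0.29 and 0.15 in KO cells, skeletal muscle markers -0.07 ± 0.20 and -0.20 and -0.14, and cartilage and bone markers 0.21 ± 0.20 and 0.14 and 0.08. By limma number 4 differed from numbers 1 and 2 in 4709 genes in 12 WT arrays and 1803 in 6 KO arrays. The difference was unequal between the lines for 1974. The arrays are unequal in number, so WT and KO counts do not compare. The fit takes conditions of the same line and number as independent, which they are not.

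**Figure D4:**
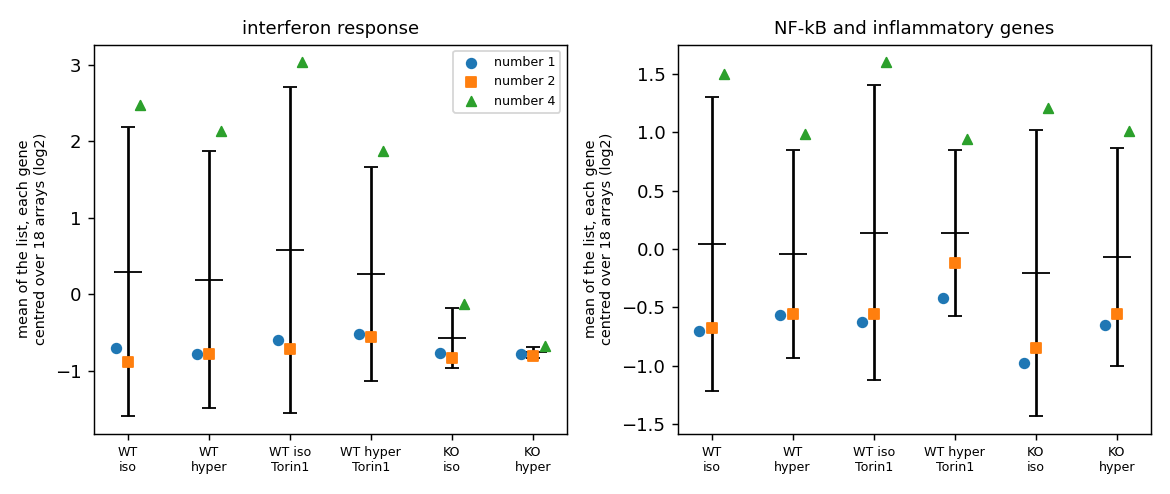
Mean level (centred log2) of the interferon response list and of the NF-kB and inflammatory list in each array, by group, points being arrays 1, 2 and 4 and bars mean ± SD of 3 arrays. Number 4 lies 3.07 above numbers 1 and 2 in WT cells for the interferon list and 0.40 above them in KO cells, and 1.78 and 1.87 for the NF-kB list.

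Cell type markers were read for a change in what the cultures contain. Of 22 extracellular matrix and fibroblast markers 0 passed under hypertonic medium in WT cells (0 higher and 0 lower, adjusted over the list alone) and 1 fell in KO cells (0 higher and 0 lower, adjusted over the list alone). No marker list of endothelial cells, macrophages, epithelium, skeletal muscle, neural cells, adipocytes or cartilage and bone passed camera for the hypertonic effect in either line. Single markers passed. In WT cells the macrophage integrin gene Itgam rose by 0.83 ± 0.22, the fatty acid carrier gene Fabp4 by 0.83 ± 0.24 and the cartilage factor gene Sox9 by 1.45 ± 0.36. The Itgam call was lost without isotonic WT array 1 (0.0704), isotonic WT array 2 (0.0659), isotonic WT array 4 (0.0936), hypertonic WT array 1 (0.163) or hypertonic WT array 2 (0.0844). The Sox9 call was lost without isotonic WT array 1 (0.0972), isotonic WT array 2 (0.0521), hypertonic WT array 1 (0.0944) or hypertonic WT array 2 (0.0506). The Fabp4 call was lost without isotonic WT array 1 (0.143), isotonic WT array 2 (0.11), isotonic Torin1 array 1 (0.053), isotonic Torin1 array 2 (0.0543), hypertonic WT array 1 (0.104), hypertonic WT array 2 (0.077), hypertonic WT array 4 (0.104), isotonic KO array 2 (0.0572), hypertonic KO array 1 (0.0525) or hypertonic KO array 2 (0.0532). In KO cells Itgam rose by 1.18 ± 0.22, the lipase gene Lpl by 1.58 ± 0.13, Fabp4 by 0.80 ± 0.24, and the endothelial adhesion genes Pecam1 and Esam by 0.47 ± 0.13 and 0.31 ± 0.10. The cadherin gene Cdh1 fell by 0.86 ± 0.22 and the osteoblast factor gene Sp7 fell by 1.30 ± 0.21. In KO cells the Fabp4 call was lost without isotonic KO array 2 (0.0556), isotonic KO array 4 (0.0712) or hypertonic KO array 1 (0.0743), and that of Pecam1 without isotonic KO array 2 (0.0584) or hypertonic KO array 4 (0.0553). The Esam call was lost without isotonic KO array 2 (0.0793), isotonic KO array 4 (0.107), hypertonic KO array 1 (0.0921) or hypertonic KO array 2 (0.121), and that of Cdh1 without isotonic KO array 1 (0.051). Counted as WT, the same array left Sox9 at 0.70 and Fabp4 at 0.31 in WT cells (limma adjusted p = 0.557 and 0.739), and in KO cells Cdh1, Lpl and Fabp4 did not pass (0.443, 0.138 and 0.224). Set against the isotonic array of its number, the hypertonic array had a higher mean of the macrophage markers in 9 of 9 pairs (by 0.06 to 0.49), though camera did not pass (adjusted p = 0.244 in WT, 0.346 with Torin1 and 0.757 in KO cells). The matrix and fibroblast markers had a lower mean in 9 of 9 pairs (-0.18 to -0.08). The mean was higher in 8 of 9 pairs for adipocyte (from -0.01 to 0.49) and endothelial markers (-0.05 to 0.38), and in 6 of 9 for epithelial (-0.16 to 0.31) and skeletal muscle markers (-0.14 to 0.24). Cartilage and bone markers had a higher mean in 5 pairs (-0.30 to 0.49) and neural markers a lower one in 7 (-0.33 to 0.08).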

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

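Splits and tests of explanations were chosen after seeing the results concerned. Patterns found and tested on the same arrays are hypotheses.

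The hypertonic response differed between KO and WT cells in 1492 genes. Those with the largest gain in KO cells were Il1f9 4.85, Ccl3 2.89, Nuak2 1.99, Plcxd2 1.72, Tnfsf18 1.67, Atp10d 1.60, Tfcp2l1 1.59 and Baz1a 1.59 (log2 difference). The largest losses were Slc5a3 -4.38, U90926 -3.44, Mrps6 -3.05, Tnfrsf22 -2.94, Prxl2a -2.89, Kcnj2 -2.79, Ddit4l -2.79 and Tnfrsf23 -2.66, and Sesn1 differed by -0.78. The Ccl3 call was lost without isotonic WT array 1 (0.084), isotonic WT array 2 (0.0801), isotonic WT array 4 (0.0678), isotonic Torin1 array 1 (0.0586), isotonic Torin1 array 2 (0.0582), isotonic Torin1 array 4 (0.0513), hypertonic WT array 1 (0.0622), hypertonic WT array 2 (0.0881), hypertonic WT array 4 (0.0796), hypertonic Torin1 array 1 (0.0577), hypertonic Torin1 array 2 (0.0562), hypertonic Torin1 array 4 (0.0522), isotonic KO array 1 (0.0968) or isotonic KO array 2 (0.0999), and its difference was 1.78 without hypertonic KO array 4. The Atp10d call was lost without isotonic WT array 4 (0.0678), hypertonic WT array 1 (0.0597), hypertonic WT array 2 (0.0819), isotonic KO array 2 (0.0663), hypertonic KO array 1 (0.0679) or hypertonic KO array 2 (0.0696), that of Kcnj2 without isotonic WT array 2 (0.058), isotonic WT array 4 (0.0628), hypertonic WT array 1 (0.0593), hypertonic WT array 2 (0.0762), isotonic KO array 4 (0.0584), hypertonic KO array 1 (0.0677) or hypertonic KO array 2 (0.076), and that of Sesn1 without isotonic WT array 2 (0.0527) or hypertonic KO array 2 (0.0563). As lists, osmolyte genes had a median difference of -0.83, FOXO targets 0.35, immediate early genes 0.28, NRF2 targets 0.31 and clock genes 0.30 (camera, with adjusted p = 0.676, 0.807, 0.943, 0.676 and 0.943 with an estimated correlation, so none of these calls holds there). With single arrays left out, the clock median ran from 0.17 to 0.51 and the immediate early one was as low as 0.13. Counting isotonic KO array 1 as WT, which mixes the lines, also ended the calls of Ccl3 (0.0781), Atp10d (0.0722), Tfcp2l1 (0.437) and Prxl2a (0.0512). With line labels exchanged within each medium, 5 of 100 splits of the 12 arrays, the real one included, called as many genes. The highest called 2771, and at a share of 0.05 that count alone does not exclude chance. The 4 others are among 7 splits that exchange 2 more arrays in 1 medium than the other and take up the line difference itself. The 47 that exchange as many in both media called 0, but mixing the lines widens their spread, so that says nothing on chance. The highest of 45 that exchange 1 more called 1215.

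With Torin1 the response differed for lists but for no single gene: osmolyte genes by a median of -0.38, sterol genes by 0.44 and DNA replication genes by 0.25 (camera, with adjusted p = 0.182, 0.966 and 0.966 with an estimated correlation, so none of these calls holds there). With single arrays left out, the osmolyte median was as low as -0.93 and the sterol median ran from 0.27 to 0.66. The DNA replication median ran from 0.09 to 0.46 with single arrays left out. The DNA replication call was also lost without any of 5 single arrays (highest 0.468). Since the real split of the 12 arrays calls 0 genes, each of 100 out of 100 splits reaches it by construction and the count says nothing on chance. Another split called 756 genes, which points to a structure of the arrays that was not traced. That split exchanges 1 more array in one medium than in the other, while the 44 splits that exchange as many in both called 0.

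Slc5a3 falls under hypertonic medium in the KO line, where the WT line raises it. The isotonic KO array with conflicting labels is argued against as the source, since the lower of the other two isotonic KO arrays still lies 0.756 above the highest hypertonic KO array. Signal of the overlapping gene Mrps6 read as Slc5a3 is argued against as the whole source, since Slc5a3 changed by -1.108 (SE 0.217) more than Mrps6. A difference between the lines other than Nfat5 cannot be told from the loss of Nfat5, with 1 line per genotype, and the fall may come from either.

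Isotonic WT array 1 lies with the Torin1 arrays on a score of genes picked on hypertonic arrays. A swap of labels with isotonic Torin1 array 1 is argued against, since that array lies at 0.989, with the other Torin1 arrays. A shift of the listed amino acid response, chaperone and sterol genes alone is argued against. On the other 184 of 200 genes the untreated array stays at 1.005. A shift that takes in unlisted genes of those kinds stays open. The array may hold RNA of cells that met Torin1, which its position of 0.959 fits, and no biological explanation was tested.

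The interferon list is high in number 4 of each WT condition. Immune cells among those cultures stay open: the 7 macrophage markers had a median difference of -0.047 but went both ways, from -0.408 to 0.671 (Cd14, with 1.785 in KO cells), several are near the floor, and no other immune cell type was tested. A scaling of those arrays is argued against, since it would move genes of the same level alike, and the interferon list lay above the 50 genes nearest in level to each member by 3.089 (SD 0.554 over the WT conditions, lowest 2.375). A difference between the lines may be involved, where number 4 lies above numbers 1 and 2 by 2.672 more in WT than in KO conditions, but the exact permutation p of 0.0667 is the smallest that 4 against 2 conditions can give. The test also treats conditions of the same line and number as independent, which they are not. Inflammatory genes such as Saa3 (6.081 in WT, 7.6 in KO) and Lcn2 (7.126 and 5.379) are high in number 4 of both lines.

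The 10 splits of 6 arrays per comparison are too few for a share under 0.05. All but the real one mix the groups, widening their spread, so low counts there say nothing on chance. The real and highest other split called 1295 and 2 genes for hypertonic WT, 530 and 0 with Torin1 and 4734 and 2 in KO. KO against WT gave 2298 and 0 in isotonic and 5007 and 0 in hypertonic medium. For Torin1 in isotonic medium the real split called 0 genes and the highest other 4, and a count of 0 is reached by 10 of 10 splits by construction. For Torin1 in hypertonic medium 2 of 10 reached the 18 genes of the real split, and the other one, with 129, sets hypertonic WT arrays 1 and 2 and hypertonic Torin1 array 2 against the rest and so follows number 4 in part, while the count with the array numbers as a block is 220.

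Probe sets without a single gene name changed as well, 84 of 8512 under hypertonic medium in WT cells (39 higher, 45 lower) and 698 in KO cells (338 higher, 360 lower), and what they measure was not analysed here.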

How the results depend on the processing

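Which alternatives were chosen before and which after the data had been seen is given above, and all were run. Counting isotonic KO array 1 as WT mixes the lines, and calls lost that way say nothing on a result. Counts are given where they moved by more than 1.5 times, and the cause of the moves was not tested.

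Genes called were, with array weights, hypertonic WT 4726, hypertonic WT with Torin1 2031, Torin1 hypertonic 1210, KO against WT isotonic 3970, KO against WT hypertonic 8403, difference with Torin1 1, difference with KO 4241. The estimation of the array weights stopped before it converged in at least 1 of these fits, so these counts are less certain. Fits on only the groups of a contrast gave hypertonic WT 267, hypertonic WT with Torin1 23, Torin1 hypertonic 0. The replicate block gave hypertonic WT 2360, hypertonic WT with Torin1 1235, Torin1 hypertonic 220, difference with KO 2280, and of 372 values of named genes not called 57 passed with it, among the genes named in advance Nfat5 for hypertonic WT (0.0154) and KO against WT hypertonic (0.00591), Slc6a6 (0.0434) and Rnf128 (0.0252) for hypertonic KO and Rnf128 for hypertonic WT with Torin1 (0.031). With isotonic KO array 1 counted as WT the counts were hypertonic WT with Torin1 315, Torin1 hypertonic 1, KO against WT isotonic 0, difference with KO 764. A replicate block within each line gave hypertonic WT 3207, hypertonic WT with Torin1 2005, Torin1 hypertonic 733, KO against WT isotonic 3935, difference with KO 3022. Without the arrays of number 4 there were hypertonic WT 3333, hypertonic WT with Torin1 1554, Torin1 hypertonic 748, KO against WT isotonic 3811, difference with Torin1 1, difference with KO 2804. The replicate block without isotonic WT array 1 gave hypertonic WT with Torin1 1390, Torin1 isotonic 295, Torin1 hypertonic 656. Quantile normalization again gave Torin1 hypertonic 29, and cyclic loess Torin1 hypertonic 28.

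Gene lists called numbered hypertonic WT 8, hypertonic WT with Torin1 5, hypertonic KO 7, Torin1 isotonic 11, Torin1 hypertonic 10, KO against WT isotonic 7, KO against WT hypertonic 5, difference with Torin1 3, difference with KO 5. They became hypertonic WT 5, hypertonic WT with Torin1 9, difference with Torin1 6 with array weights, hypertonic WT 5, hypertonic WT with Torin1 3, difference with Torin1 5, difference with KO 3 with isotonic KO array 1 as WT, hypertonic WT with Torin1 8 after quantile normalization, hypertonic WT with Torin1 9 after cyclic loess, and hypertonic WT with Torin1 8 on only the groups of the contrast. Arrays centred on their medians gave hypertonic KO 4, difference with KO 3, the 50th percentile filter KO against WT hypertonic 8, and the replicate block KO against WT hypertonic 8. A block within each line gave hypertonic WT with Torin1 9, KO against WT hypertonic 9, the arrays of number 4 left out hypertonic WT with Torin1 10, difference with Torin1 5, and the replicate block without isotonic WT array 1 KO against WT isotonic 11, KO against WT hypertonic 9, difference with Torin1 6. The estimated correlation, with or without the replicate block, left 0 lists in all 9 comparisons. Further list calls lost were, for hypertonic WT, heat shock with array weights (0.0698), p53 with array weights (0.275), with isotonic KO array 1 as WT (0.0504) and with the replicate block without isotonic WT array 1 (0.063), and actin with isotonic KO array 1 as WT (0.214). That assignment also ended osmolyte (0.0698) and p53 (0.0643) for hypertonic WT with Torin1 and immediate early for KO against WT isotonic (0.145). ATF4 for hypertonic WT was lost with array weights (0.797), only the groups (0.0835), isotonic KO array 1 as WT (0.0804) and the replicate block without isotonic WT array 1 (0.598). NF-kB for KO against WT isotonic was lost in 10 settings, from 0.0579 with cyclic loess to 0.912 with isotonic KO array 1 as WT. DNA replication for the difference with Torin1 was lost with array weights (0.0701) and without number 4 (0.85), and p53 for Torin1 hypertonic with array weights (0.0609).

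Leaving out each array in turn, genes called ran from 534 to 1835 for hypertonic WT, 161 to 675 for hypertonic WT with Torin1, 3796 to 4933 for hypertonic KO, 0 to 25 for Torin1 isotonic, 0 to 148 for Torin1 hypertonic, 1723 to 2456 for KO against WT isotonic, 3823 to 5236 for KO against WT hypertonic, 0 to 0 for difference with Torin1, 832 to 1745 for difference with KO. Lists called ran from 6 to 8 for hypertonic WT, 3 to 9 for hypertonic WT with Torin1, 6 to 8 for hypertonic KO, 9 to 15 for Torin1 isotonic, 6 to 12 for Torin1 hypertonic, 5 to 11 for KO against WT isotonic, 5 to 8 for KO against WT hypertonic, 3 to 8 for difference with Torin1, 3 to 8 for difference with KO. Of 364 called values of named genes 364 stayed called with the replicate block, 363 with array weights, 357 with cyclic loess, 350 with centring on medians, 269 on only the groups of the contrast and 213 with isotonic KO array 1 as WT, and leaving out 1 array lost 14 to 56. No call changed its direction under any setting. Both response scores kept their sign, from -0.111 to -0.0191 for Torin1 and -0.342 to -0.131 for KO with 1 array left out, and pairing the exact test by number gave p = 0.25 for each.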

Other observations

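The imprinted and Dlk1-Dio3 gene sets and the sex-linked levels below were chosen after values had been seen. The Dlk1-Dio3 interval holds imprinted noncoding transcripts, among them Meg3 and Rian and many microRNA genes, which can be read from shared precursors. Under hypertonic medium Meg3 fell in WT (-0.80 ± 0.13), in WT with Torin1 (-0.72 ± 0.13) and in KO cells (-0.53 ± 0.13), and the microRNA gene Mir377 fell as well (-1.30 ± 0.17, -1.32 ± 0.17 and -2.75 ± 0.17). Of 37 measured genes of the interval 14 fell in WT cells, 37.8% against 4.22% of other genes (Fisher exact p = 1.59e-10), 9 with Torin1 (24.3% against 1.67%, Fisher exact p = 9.35e-09) and 31 in KO cells (83.8% against 17.1%, Fisher exact p = 1.39e-18), and none rose. Their medians were -0.48, -0.42 and -0.89. Members that share a transcript are not independent, and the set was prompted by values on the same arrays, so these p-values are too small.

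Some imprinted genes differed between the lines in isotonic medium, with the growth factor gene Igf2 higher in KO cells by 4.46 ± 0.25 (from 7.89 to 12.35), Sgce by 5.04 ± 0.13 and its neighbour Peg10 by 4.01 ± 0.24, the amino acid transporter gene Slc38a4 by 4.88 ± 0.33 and the growth regulator Plagl1 by 1.94 ± 0.18. Of 33 measured imprinted genes 8 were higher in KO cells, 24.2% against 7.75% of other genes, 2 were lower and 23 did not pass, among them Peg3, Grb10 and Igf2r. In hypertonic medium 9 were higher, 27.3% against 13.8% of other genes, 2 were lower (Ndn by -1.23 ± 0.31 and Impact by -0.64 ± 0.16) and 22 did not pass. The set was prompted by the genes named here and holds neighbours such as Sgce and Peg10, so no p-value is given for these shares.

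Both lines read as male: the Y-linked genes Eif2s3y and Kdm5d lay at 10.44 and 9.54 in isotonic WT and 10.60 and 9.60 in isotonic KO cells, and Xist, the transcript of the silent X chromosome, at 5.22 and 5.33.

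The loss of Slc5a3 induction in KO cells starts from a high level, 11.51 ± 0.36 (SD) in isotonic KO against 8.56 ± 0.27 in isotonic WT cells, and ends at 9.99 ± 0.49 in hypertonic KO cells, above the isotonic WT level. The overlapping gene Mrps6 is higher in isotonic KO cells too (2.07 ± 0.29), and what holds both up there was not tested.

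Isotonic WT array 1, at 0.959 on the Torin1 score, may explain why no gene passed for Torin1 in isotonic medium. The 295 genes called without it and with a block rest on a choice made after seeing it. New untreated cultures could test them.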
